A study of Solanum lycopersicum with 9 samples.

How the data were processed

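Per the labels, RNA was extracted from tomato (Solanum lycopersicum) seeds after 6 h of imbibition with the RNeasy mini plus kit, and libraries were made with the SMARTER mRNA-Seq kit. There were 9 libraries in 3 groups, with 3 each of WT, SlLBD40 knockout and SlWRKY37 knockout seeds, and each library carried a replicate number.

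The authors name TopHat2, HISAT2, StringTie and Cufflinks, without versions, order or role. The genome build and the annotation are not given in the sources used here. The deposited table holds gene expression values with 2 decimals that were taken as FPKM (fragments scaled by transcript length and by the mapped fragments of a library). No header states this unit. It was inferred from values that are not whole, that sum to different totals below 1000000 and that come from tools which write FPKM. The column of WT replicate 1 in the deposited table touches the column of gene names, so that its unit is recorded as other; read by character position it holds the same quantity. TPM of the listed genes alone is ruled out by the totals, but TPM over a larger gene set is not.

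The table has 40229 rows, of which 34075 carry an ID of a protein-coding gene and 6154 an ID of an RNA gene. Gene IDs were shortened to 8 characters by the fixed width of the table, and 3666 full IDs can be read. Genes are therefore named by their description and by the chromosome in the shortened ID. Copy numbers count the genes that share a description and a chromosome in the order of the table, and are not official names. Unplaced sequence is chromosome 0 in the IDs. Of the rows, 29223 were above 0 in at least 1 library. Among tested genes, 22 had the same 9 values as another gene.

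Genes with a mean of at least 1 over the 9 libraries were tested (18346). Values were put on the log2(value + 1) scale and fitted with limma 3.58.1 in R 4.3.3 (limma-trend, robust off), all 9 libraries in 1 fit with genotype as the only term. Contrasts were each knockout minus WT and the LBD40 minus the WRKY37 knockout. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and adjusted values below 0.05 were called. The pseudocount of 1 makes fold changes of low genes smaller than the ratio of their means, which is why levels are printed. Plots were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.

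Gene lists were fixed before the data were examined, as text patterns searched in the descriptions. Lists with at least 5 tested genes (24) were tested with camera at a preset correlation between genes of 0.01, adjusted over the 24 lists of a contrast. The plan named this test for the 2 contrasts with WT; it was also run between the knockouts. As alternatives, camera was run with the correlation estimated from the data, and fry, which asks whether a set's genes move, on balance, one way without comparing them with other genes. A further 12 lists were narrowed from these after the descriptions had been read. A list of aquaporins had 1 tested gene of 3 found, and lists that needed full gene IDs (ripe fruit markers, organelle-encoded transcripts) could not be searched, so none of these was tested.

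Named genes were chosen by a rule fixed before the data were examined. They were the targeted genes; in each knockout the 10 higher and 10 lower called genes with the largest log2 change, no overlap with WT, a mean of at least 5 in the higher group and an informative description; up to 4 called members with the smallest adjusted p of each list that passed or had at least 3 called members; the 5 higher and 5 lower genes changed in both knockouts with the smallest larger adjusted p; and the 5 highest and 5 lowest between the knockouts. A part of the rule that named hormone genes by ID could not be used, since these IDs are shortened. The IDs recalled in the plan for the targeted genes lie on chromosome 2 and could not be matched for the same reason. A reference gene table lists SlWRKY37 as another name of a gene on chromosome 1, so which gene was edited was not settled here.

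Genes called in both knockouts were counted by direction and set beside the product of the list sizes over the number tested. They were also compared with 100 simulated draws in which unchanged groups were compared with the same WT libraries. The WT libraries are too few to be split so that each knockout has its own pair. Shares of a library are sums of values over the library total. Single values were compared with two-sided exact permutation tests, for which 3 against 3 cannot go below 0.1.

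Alternatives were a pseudocount of 0.1, quantile normalization, a minimum mean of 5, no low-value filter, a fit of only the 2 groups compared, the replicate number as a block, a minimum log2 change of 1 and leaving out each library in turn. Scaling to equal library totals and median-ratio scaling were added after the data were seen. Same-numbered libraries were not treated as pairs: of 9 pairs of libraries with the same number, the correlation of their deviations from the group mean lay between -0.105 and 0.063. The fit was also tested on simulated data of 18346 genes, of which 68, 66 and 66 were changed by 0.5, 1 and 2 on the log2 scale. It recovered 11.8, 72.7 and 95.5% of them in the LBD40 contrast and 8.82, 62.1 and 93.9% in the WRKY37 contrast, with 4 and 2 false calls. Far more genes were called in the real data, which shifts the adjusted threshold, so these rates do not carry over to it. The depth of the libraries is unknown, as the values do not give read counts.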

Results

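RNA was sequenced from tomato seeds after 6 h of imbibition, the uptake of water that starts germination. The 9 libraries fell into 3 groups of 3, which were wild type (WT), seeds of an SlLBD40 knockout line and seeds of an SlWRKY37 knockout line. SlLBD40 belongs to the LOB domain family and SlWRKY37 to the WRKY family, both families of plant transcription factors. Values are expression values taken as FPKM, given as mean ± SD of 3 libraries (n = 3). TPM over a larger gene set is not excluded. Genes are named by their description and chromosome, with a copy number where several genes on a chromosome share a description.

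The summed expression value per library lay between 856291 and 918103, and 23206 to 24507 genes had a value above 0. The 10 most abundant transcripts took 8.24 to 9.76% of the sum in the WT libraries, 6.03 to 6.89% in the LBD40 knockout and 6.03 to 8.49% in the WRKY37 knockout. The data give no read counts, so the depth behind a value is unknown and no counting interval is given. Across 18346 genes, the correlation between 2 libraries was 0.9596 to 0.9778 within a group and 0.9083 to 0.9529 between groups; these are correlations across genes, which are not independent replicates. The labels do not say whether the libraries of a group came from separate plants or seed lots, so the p-values measure the spread between these samples only. For every gene named here with a called change, all 3 libraries of one group lay beyond all 3 of the other.

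The first comparison asked how the transcripts of imbibed seeds of the SlLBD40 knockout line differ from those of WT seeds. Seeds of the LBD40 knockout held lower RNA levels for oil body proteins, which coat the oil stores of the seed, and higher RNA levels for histones, which package DNA, and for enzymes that loosen or hydrolyse the cell wall. These 3 lists passed camera with its preset correlation (adjusted p = 1.96e-05, 6.87e-08 and 1.39e-09), and each had an adjusted p = 0.508 with an estimated correlation. Of 15 oil body genes 13 fell and 1 rose, of 55 histone genes 35 rose and 7 fell, and of 129 cell wall genes 63 rose and 6 fell. The oil body gene oleosin S1-2-like on chromosome 7 fell from 234 ± 50.9 to 13 ± 1.61, a ratio of 18. Among single genes, vicilin on chromosome 9, a storage protein, fell from 5910 ± 822 to 419 ± 71.6, and alcohol dehydrogenase-2 on chromosome 9, an enzyme of fermentation, fell from 963 ± 236 to 60.1 ± 18.8.

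In all, 6826 of 18346 genes passed the test in the LBD40 knockout (37.2%), 3296 of them higher and 3530 lower. Of these, 2005 also differed by at least 1 on the log2 scale, 1248 higher and 757 lower. Without replicate 1 of the LBD40 knockout 4533 genes passed, 2426 higher and 2107 lower, and without WT replicate 2 the higher genes (2587) also outnumbered the lower (2294). The median log2 change of all genes was -0.023.

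The oil body list had a median log2 change of -1.25 (camera adjusted p = 1.96e-05). Its members included Oleosin on chromosome 12, which fell from 1380 ± 182 to 579 ± 90.1, and Oleosin on chromosome 3 (copy 1), which fell from 2880 ± 457 to 803 ± 69.9. One of its 15 genes did not pass, and adjusted over the list alone the counts were 1 higher and 13 lower. The list had an adjusted p = 0.508 with an estimated correlation between genes. Its share of the library total was 1.14 ± 0.167% in WT and 0.508 ± 0.0568% in the knockout, and with 3 libraries against 3 an exact test cannot give a p below 0.1.

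Genes of late embryogenesis abundant (LEA) proteins and dehydrins, which are made as seeds dry, went both ways. Of 67 tested, 24 fell, 14 rose and 29 did not pass. The list did not pass camera (median -0.045, adjusted p = 0.167) but passed as lower with fry (adjusted p = 0.0065; 15 higher and 25 lower adjusted over the list alone). The most abundant members fell: 11 kDa late embryogenesis abundant protein on chromosome 10 (copy 1) from 25800 ± 3940 to 5650 ± 826, and Dehydrin on chromosome 2 from 4540 ± 483 to 1640 ± 179. The summed LEA share of the library was 6.73 ± 0.712% in WT and 2.53 ± 0.296% in the knockout. Seed storage proteins, the nitrogen reserve of the embryo and endosperm, likewise went both ways, with 9 higher, 11 lower and 14 not called of 34 (median -0.147, camera adjusted p = 0.491; 9 and 11 adjusted over the list alone). The storage median ranged from -0.294 without WT replicate 1 to 0.111 without WT replicate 3. The vicilin-like seed storage protein At2g18540 on chromosome 2 fell from 356 ± 51 to 107 ± 5.78, and the Vicilin-like antimicrobial peptides 2-1 gene on chromosome 9 fell from 876 ± 161 to 68.1 ± 29.4. Both text patterns also took in wider families, and lists narrowed after the data were seen were mostly lower. LEA genes outside the hydroxyproline-rich family had 6 higher and 23 lower of 45 (median -0.646, camera adjusted p = 0.000477). Storage proteins outside the lipid-transfer family had 1 higher and 8 lower of 12 (median -2.35, camera adjusted p = 3.34e-05). Both had an adjusted p = 0.273 with an estimated correlation.

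Histone genes had a median log2 change of 0.98 (camera adjusted p = 6.87e-08; 36 higher and 7 lower adjusted over the list alone), and 13 did not pass. Histone H4 on chromosome 6 (copy 5) rose from 36.7 ± 12 to 157 ± 18.5, and Histone H3 on chromosome 12 rose from 4.61 ± 1.23 to 28.6 ± 5.49. With an estimated correlation the histone list had an adjusted p = 0.508. Genes of the cell cycle and of DNA replication did not move together, with 14 higher, 23 lower and 69 not called of 106 (adjusted p = 0.813; 13 and 23 adjusted over the list alone; median -0.013, mean 0.023, test towards lower). In that list cyclin A2 on chromosome 6 rose from 6.41 ± 1.71 to 16 ± 1, and Cyclin-dependent kinase inhibitor on chromosome 12 fell from 132 ± 16.1 to 69.6 ± 2.17.

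Cell wall genes had a median log2 change of 0.776 (camera adjusted p = 1.39e-09; 65 higher and 6 lower adjusted over the list alone), and 60 did not pass. The Mannan endo-1,4-beta-mannosidase 1 genes on chromosome 2 (copies 2 and 3), enzymes that break down the mannan of seed cell walls, both rose from 0.657 ± 0.666 to 13.6 ± 4.42, with the same value in every library. Xyloglucan endotransglucosylase-hydrolase 9 on chromosome 12, which remodels wall xyloglucan, rose from 9.83 ± 11.1 to 67.8 ± 17.6. Glucan endo-1,3-beta-glucosidase on chromosome 7 rose from 23.6 ± 1.97 to 76.4 ± 4.29, and Pectinesterase on chromosome 3 (copy 7) from 34.7 ± 3.29 to 111 ± 12.4. The list had an adjusted p = 0.508 with an estimated correlation.

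Photosynthesis genes, held as markers of green tissue, had 15 of 56 members higher, 0 lower and 41 not called (median 0.54, camera adjusted p = 0.00488; 12 higher and 0 lower adjusted over the list alone). Ribulose bisphosphate carboxylase small chain on chromosome 7 rose from 2.63 ± 0.96 to 12.2 ± 1.66. The list's share of the library was 0.0664 ± 0.0248% in WT, with 0.0948% in replicate 3 alone, and 0.102 ± 0.0131% in the knockout. The call was lost without WT replicate 2 (median 0.36, adjusted p = 0.0894), and the list had an adjusted p = 0.624 with an estimated correlation.

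Further lists that act in metabolism were higher in camera. The list of lipid mobilisation and the glyoxylate cycle had 33 of 97 genes higher, 14 lower and 50 not called (median 0.352, adjusted p = 0.00293; 38 and 14 adjusted over the list alone; adjusted p = 0.569 with an estimated correlation). The 4 members with the smallest p were GDSL-type lipases, a family that acts on many esters and is not tied to oil reserves, and GDSL esterase/lipase on chromosome 3 (copy 6) rose from 9.39 ± 2.62 to 55.2 ± 7.16. Peroxidases and other enzymes of reactive oxygen had 25 of 65 genes higher, 3 lower and 37 not called (median 0.427, adjusted p = 0.00419; 25 and 3 adjusted over the list alone; adjusted p = 0.508 with an estimated correlation). Respiratory burst oxidase-like protein on chromosome 1, a producer of superoxide, rose from 5.94 ± 3.3 to 44.4 ± 12.4, and superoxide dismutase 3 on chromosome 11 rose from 31.7 ± 3.4 to 83.5 ± 7.8. Starch and raffinose sugar genes had 26 of 69 higher, 12 lower and 31 not called (median 0.346, adjusted p = 0.0192; 27 and 12 adjusted over the list alone; adjusted p = 0.508 with an estimated correlation). In that list Alpha-galactosidase on chromosome 4 rose from 13.2 ± 0.705 to 34.7 ± 3.42, while the alkaline alpha-galactosidase seed imbibition protein on chromosome 7 fell from 13.6 ± 2.14 to 1.58 ± 0.376.

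Regulatory and stress lists were also higher in camera. WRKY transcription factors had 11 of 32 genes higher, 2 lower and 19 not called (median 0.422, adjusted p = 0.00269; 14 and 2 adjusted over the list alone), and WRKY transcription factor 53 on chromosome 8 rose from 2.94 ± 0.257 to 11.1 ± 0.516. Jasmonate genes had 13 of 26 higher, 2 lower and 11 not called (median 0.577, adjusted p = 0.0131; 15 and 3 adjusted over the list alone), and jasmonate ZIM-domain protein 1 on chromosome 12, a repressor of jasmonate responses, rose from 1.23 ± 0.249 to 5.82 ± 1.74. Small heat shock proteins had 9 of 33 higher, 2 lower and 22 not called (median 0.304, adjusted p = 0.0204; 8 and 2 adjusted over the list alone), and small heat shock protein 1 on chromosome 5 rose from 32.7 ± 7.27 to 82.6 ± 7.91. Each of these 3 lists had an adjusted p = 0.508 with an estimated correlation. The small heat shock call was lost without WT replicate 2 (adjusted p = 0.0555) or LBD40 knockout replicate 2 (adjusted p = 0.0663).

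Lists of other hormones did not pass camera in the LBD40 knockout. Abscisic acid genes had 26 higher and 22 lower of 100 (adjusted p = 0.508; 28 and 22 adjusted over the list alone), and ABSCISIC ACID-INSENSITIVE 5-like protein 5 on chromosome 1, of a family of transcription factors that respond to abscisic acid, fell from 46.6 ± 5.21 to 13.9 ± 2.26. The pattern of the abscisic acid list takes in every gene described as protein phosphatase 2C. Without these, in a list narrowed after the data were seen, 8 were higher and 7 lower of 32 (camera adjusted p = 0.4). Gibberellin genes had 10 higher and 5 lower of 27 (adjusted p = 0.149; 12 and 5 adjusted over the list alone) and passed as higher with fry (adjusted p = 0.0406), and gibberellin 2-oxidase 2 on chromosome 7, which inactivates gibberellins, rose from 1.23 ± 0.673 to 5.59 ± 0.39. Ethylene genes had 25 higher and 19 lower of 94 (adjusted p = 0.612; 26 and 20 adjusted over the list alone; median -0.017, mean 0.067, test towards higher), and 1-aminocyclopropane-1-carboxylate oxidase 2 on chromosome 12, which makes ethylene, rose from 0.433 ± 0.338 to 10.9 ± 2.9. Auxin genes had 18 higher and 11 lower of 95 (adjusted p = 0.404; 18 and 10 adjusted over the list alone).

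The remaining lists did not pass camera either. Large heat shock chaperones had 12 higher and 29 lower of 128 (adjusted p = 0.149; 11 and 24 adjusted over the list alone), and Heat shock 70 kDa protein on chromosome 7 fell from 277 ± 98.1 to 18.9 ± 5.97. Heat stress transcription factors had 5 higher and 5 lower of 20 (adjusted p = 0.88; 6 and 5 adjusted over the list alone). LOB domain genes had 6 higher and 2 lower of 15 (adjusted p = 0.167; 6 and 2 adjusted over the list alone; median 0.408 and adjusted p = 0.0471 without WT replicate 1), and LOB domain-containing protein 38 on chromosome 1 rose from 0.283 ± 0.248 to 7.07 ± 2.76. Flavonoid genes had 6 higher and 1 lower of 15 (adjusted p = 0.214; 6 and 1 adjusted over the list alone), and glutathione S-transferases 13 higher and 8 lower of 51 (adjusted p = 0.569; 14 and 9 adjusted over the list alone). Proteinase inhibitors and pathogenesis-related proteins had 13 higher and 11 lower of 55 (adjusted p = 0.271; 15 and 11 adjusted over the list alone). Cytosolic ribosomal proteins had 14 higher and 11 lower of 202 (adjusted p = 0.491; 0 and 1 adjusted over the list alone).

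Among single genes with the largest changes, SNF2 domain-containing protein CLASSY 4-like on chromosome 1, of a family that directs DNA methylation, rose from 0.203 ± 0.136 to 22.9 ± 3.9 (adjusted p = 3.51e-06). Homeobox-leucine zipper protein ROC5 on chromosome 6 (copy 3), of a family of epidermal regulators, fell from 34.1 ± 0.462 to 0.0267 ± 0.0306. It was also low in the WRKY37 knockout libraries, at 0.03, 4.28 and 0. The tyrosine sulfotransferase-like protein on chromosome 12 (copy 1) had 16.6 ± 5.97 in WT and was listed at 0 in all 3 knockout libraries. DNA-directed RNA polymerase subunit beta'' on unplaced sequence, a protein coded in plastids, rose from 2.49 ± 2.54 to 45 ± 11.3.

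**Figure D1:**
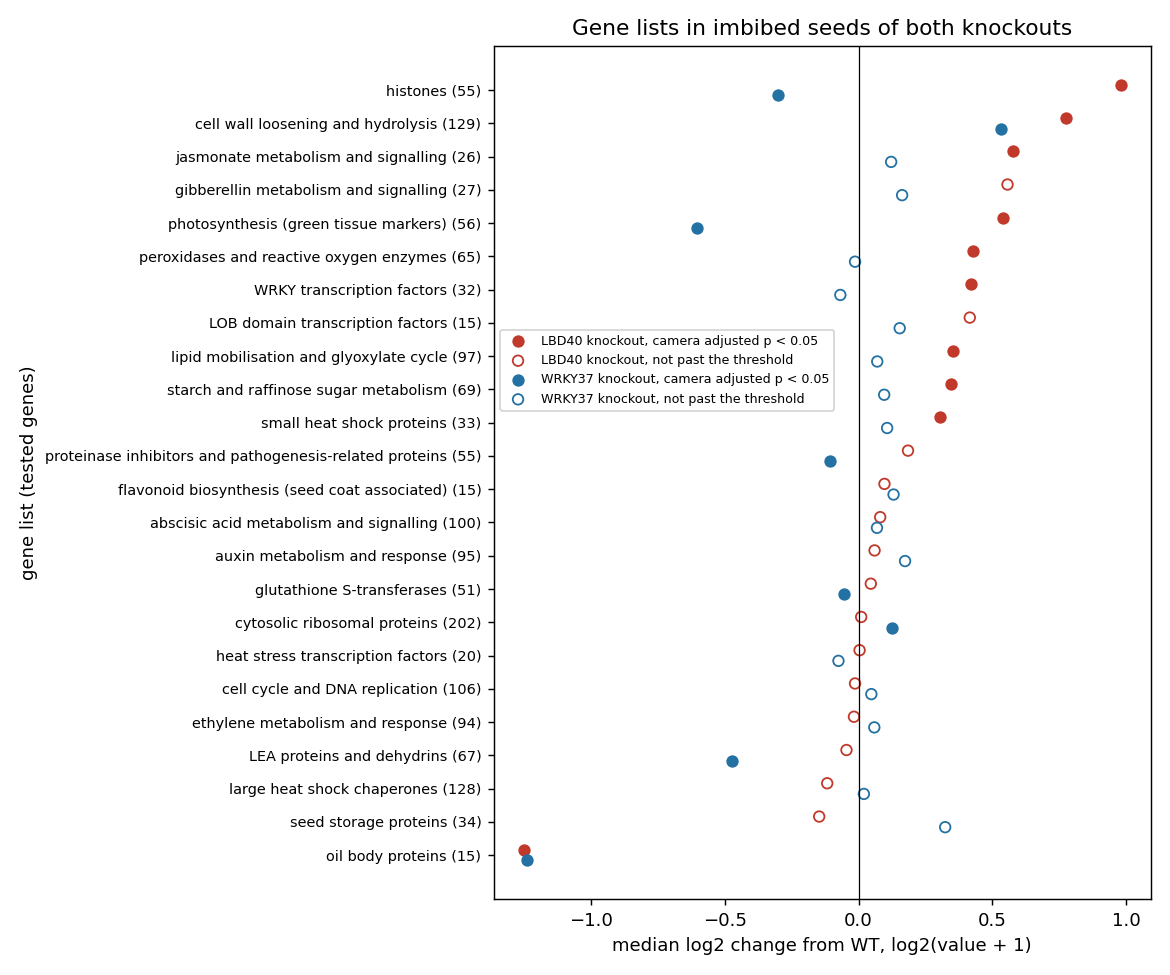
Median log2 change from WT, on log2(value + 1), of the 24 gene lists in the LBD40 knockout (red) and the WRKY37 knockout (blue), with the number of tested genes after each name. Filled points passed the camera test with the preset correlation (10 and 8 lists) and open points did not. With an estimated correlation 0 lists passed in either knockout. The oil body medians lie at -1.25 and -1.24, and the histone medians at 0.98 and -0.3.

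The second comparison asked how imbibed seeds of the SlWRKY37 knockout line differ from WT seeds. In camera with its preset correlation, the lists of oil body proteins, LEA proteins, histones and photosynthesis were lower and that of cell wall enzymes higher in this knockout. With an estimated correlation these 5 lists had adjusted p = 0.318, 0.093, 0.626, 0.731 and 0.731. Of 15 oil body genes 12 fell and 0 rose, of 67 LEA genes 27 fell and 4 rose, of 129 cell wall genes 34 rose and 5 fell, of 55 histone genes 13 fell and 1 rose, and of 56 photosynthesis genes 9 fell and 2 rose. Defensin protein on chromosome 7 (copy 5), an antimicrobial peptide, fell from 193 ± 83.9 to 8.71 ± 1.59, and Glutathione S-transferase on chromosome 1 (copy 1), a detoxifying enzyme, rose from 27.9 ± 6.85 to 388 ± 66.1.

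In all, 1721 of 18346 genes passed the test in the WRKY37 knockout (9.38%), 884 higher and 837 lower, and 816 of them differed by at least 1 on the log2 scale, 386 higher and 430 lower. The number and the balance of directions depended on single libraries. Without WT replicate 1 it was 783 (345 higher, 438 lower), without WT replicate 3 951 (414 and 537), without WRKY37 knockout replicate 1 1134 (479 and 655) and without WRKY37 knockout replicate 3 2629 (1693 and 936). With the LBD40 libraries left out of the fit, 802 genes passed, 367 higher and 435 lower. The median log2 change of all genes was 0.022.

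The oil body list had a median log2 change of -1.24 (camera adjusted p = 8.15e-11; 0 higher and 13 lower adjusted over the list alone; adjusted p = 0.318 with an estimated correlation), and 3 genes did not pass. Oleosin on chromosome 12 fell from 1380 ± 182 to 509 ± 99.8, and oleosin S1-2-like on chromosome 7 fell from 234 ± 50.9 to 36.1 ± 16.5. The list's share of the library was 0.513 ± 0.178%, with 0.717% in replicate 3, against 1.14 ± 0.167% in WT. LEA genes had a median of -0.473 (adjusted p = 9.81e-07; 7 higher and 31 lower adjusted over the list alone; adjusted p = 0.093 with an estimated correlation), and 36 did not pass. The LEA median was -0.294 without WT replicate 1 or WT replicate 3. Late embryogenesis abundant protein 6 on chromosome 6 fell from 916 ± 99.8 to 261 ± 26.7, and Late embryogenesis abundant protein on chromosome 9 (copy 1) from 1110 ± 28 to 335 ± 93.5. The summed LEA share was 2.95 ± 0.597% against 6.73 ± 0.712% in WT.

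Seed storage proteins as a list did not pass camera, with 7 higher, 5 lower and 22 not called of 34 (median 0.324, adjusted p = 0.485; 15 and 7 adjusted over the list alone). The vicilin-like seed storage protein At2g18540 on chromosome 2 fell from 356 ± 51 to 88 ± 7.89, while a lipid transfer and seed storage helical domain protein on chromosome 1 rose from 30.4 ± 3.17 to 69.8 ± 0.427. A list narrowed after the data were seen, without the lipid-transfer family, had 0 higher and 4 lower of 12 (median -1.246, camera adjusted p = 2.92e-05). Its adjusted p was 0.411 with an estimated correlation. Replicate 3 of the WRKY37 knockout stood apart here: vicilins and other storage proteins outside the lipid-transfer family took 1.01% of that library, against 0.195 and 0.264% in replicates 1 and 2 and 0.997 ± 0.141% in WT.

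Cell wall genes had a median log2 change of 0.533 (adjusted p = 7.83e-07; 49 higher and 7 lower adjusted over the list alone; adjusted p = 0.731 with an estimated correlation), and 90 did not pass. The median was 0.315 without WRKY37 knockout replicate 1. Replicate 3 of the knockout had a share of 0.25%, near the 0.231 ± 0.0277% of WT, against 0.364 and 0.322% in replicates 1 and 2. Mannan endo-1,4-beta-mannosidase 1 on chromosome 4 rose from 23.9 ± 3.99 to 124 ± 42.4 and Endoglucanase on chromosome 1 (copy 2) from 0.847 ± 0.185 to 6.67 ± 1.77. In the opposite direction, xyloglucan endotransglycosylase on chromosome 9 fell from 40.1 ± 11.3 to 6.15 ± 2.18.

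Histone genes had 1 of 55 higher, 13 lower and 41 not called (median -0.3, adjusted p = 8.56e-07; 2 and 18 adjusted over the list alone; adjusted p = 0.626 with an estimated correlation). The histone median was -0.185 without WT replicate 3. Histone H4 on chromosome 6 (copy 7) fell from 743 ± 32.6 to 379 ± 51.6 and Histone H2A on chromosome 12 (copy 1) from 204 ± 18.1 to 117 ± 5.29. Photosynthesis genes had 2 of 56 higher, 9 lower and 45 not called (median -0.602, adjusted p = 4.03e-05; 4 and 18 adjusted over the list alone; adjusted p = 0.731 with an estimated correlation). Without WT replicate 3, the WT library with the largest photosynthesis share (0.0948%), the median was -0.314. The photosystem I reaction center subunit psaK gene on chromosome 8 fell from 7.03 ± 4.9 to 0.733 ± 0.667, whereas Photosystem I P700 chlorophyll a apoprotein A2 on chromosome 2, a protein coded in plastids, was listed at 0 in all WT libraries and had 8.27 ± 5.6 in the knockout.

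In camera, a pair of defence and detoxification lists was lower, although most of their genes were not called. Glutathione S-transferases had 2 of 51 higher, 12 lower and 37 not called (median -0.055, adjusted p = 0.00287; 3 and 16 adjusted over the list alone; adjusted p = 0.626 with an estimated correlation), and Glutathione S-transferase on chromosome 10 (copy 3) fell from 341 ± 37 to 131 ± 24.5. Their median was small and unsteady, at -0.16, -0.254 and -0.152 without WT replicates 1, 2 and 3, and at -0.256, -0.151 and -0.033 without WRKY37 knockout replicates 1, 2 and 3. Proteinase inhibitors and pathogenesis-related proteins had 1 of 55 higher, 10 lower and 44 not called (median -0.106, adjusted p = 0.00733; 2 and 11 adjusted over the list alone; adjusted p = 0.318 with an estimated correlation), and acidic extracellular 26 kD chitinase on chromosome 2 fell from 58.8 ± 9.11 to 10 ± 2.95. Their median was -0.187 without WT replicate 3 and -0.021 without WRKY37 knockout replicate 3, and their share of the library was 0.258 and 0.272% in replicates 1 and 2 and 0.505% in replicate 3, against 0.513 ± 0.0726% in WT. Both calls were lost without WRKY37 knockout replicate 2, at medians of -0.151 and -0.189 and adjusted p = 0.144 and 0.131.

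Cytosolic ribosomal proteins, with a median of 0.124, passed as a list (adjusted p = 0.00105), though 4 of 202 rose and 1 fell, and 0 passed in either direction adjusted over the list alone. The list had an adjusted p = 0.941 with an estimated correlation. The call was lost without WT replicate 1 (median 0.063, adjusted p = 0.112) or WRKY37 knockout replicate 2 (median 0.02, adjusted p = 0.131).

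Hormone lists did not pass camera in the WRKY37 knockout. Abscisic acid genes had 7 higher and 6 lower of 100 (adjusted p = 0.709; 14 and 10 adjusted over the list alone), and ABSCISIC ACID-INSENSITIVE 5-like protein 7 on chromosome 1 fell from 30.8 ± 9.93 to 7.63 ± 0.968. Without genes described as protein phosphatase 2C, 5 were higher and 3 lower of 32 (camera adjusted p = 0.585). Gibberellin genes had 3 higher and 3 lower of 27 (adjusted p = 0.485; 7 and 4 adjusted over the list alone), and Gibberellin-regulated protein on chromosome 6 rose from 18.9 ± 4.24 to 74.8 ± 18. Jasmonate genes had 3 higher and 2 lower of 26 (adjusted p = 0.53; 5 and 2 adjusted over the list alone), and Protein TIFY 10A on chromosome 3 fell from 6.65 ± 0.827 to 1.65 ± 0.292. Ethylene genes had 8 higher and 14 lower of 94 (adjusted p = 0.563; 9 and 18 adjusted over the list alone; median 0.059, mean -0.113, test towards lower), and auxin genes 7 higher and 6 lower of 95 (adjusted p = 0.265; 11 and 6 adjusted over the list alone).

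The other lists did not pass camera in this comparison. WRKY transcription factors had 1 higher and 4 lower of 32 (adjusted p = 0.293; 1 and 4 adjusted over the list alone), and WRKY transcription factor 6 on chromosome 2 fell from 11.9 ± 1.73 to 2.98 ± 1.51. LOB domain genes had 0 called of 15 (adjusted p = 0.485; 0 adjusted over the list alone). Small heat shock proteins had 8 higher and 1 lower of 33 (adjusted p = 0.0895; 10 and 3 adjusted over the list alone), a list that passed without WT replicate 1 (adjusted p = 0.0286) or without WRKY37 knockout replicate 1 (adjusted p = 0.0361) or 2 (adjusted p = 0.00853). Lipid mobilisation genes had 12 higher and 4 lower of 97 (adjusted p = 0.44; 17 and 5 adjusted over the list alone). Starch and raffinose sugar genes had 10 higher and 8 lower of 69 (adjusted p = 0.693; 13 and 10 adjusted over the list alone). Peroxidase and reactive oxygen genes had 3 higher and 4 lower of 65 (adjusted p = 0.644; 4 and 6 adjusted over the list alone), and Peroxidase on chromosome 2 (copy 18) fell from 29.3 ± 10.8 to 1.69 ± 1.1.

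No call was made either for lists of the cell cycle, of chaperones or of flavonoids. Cell cycle and DNA replication genes had 5 higher and 5 lower of 106 (adjusted p = 0.709; 5 and 5 adjusted over the list alone), and DNA replication licensing factor MCM7 on chromosome 1 rose from 14.1 ± 2.3 to 34.1 ± 8.97. Large heat shock chaperones had 2 higher and 5 lower of 128 (adjusted p = 0.928; 2 and 5 adjusted over the list alone; median 0.02, mean -0.005, test towards lower). Heat stress transcription factors had 1 higher and 1 lower of 20 (adjusted p = 0.928; 2 and 1 adjusted over the list alone; median -0.075, mean 0.049, test towards lower), and flavonoid genes 0 higher and 1 lower of 15 (adjusted p = 0.928; 0 and 2 adjusted over the list alone).

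**Figure D2:**
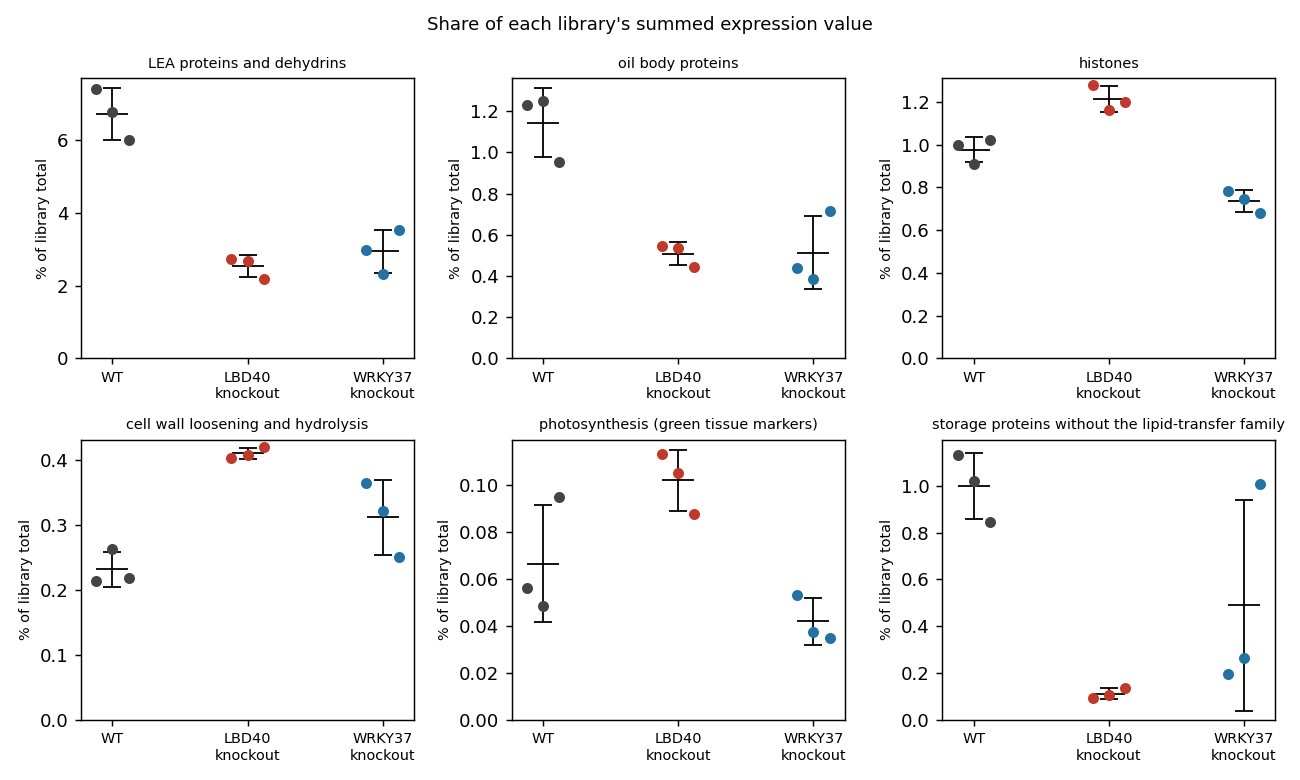
Share of the summed expression value of each library taken by 6 gene groups, in percent. Points are libraries, in the order of their replicate numbers, and lines with bars are mean ± SD of 3 libraries; LEA transcripts took 6.73% in WT against 2.53 and 2.95% in the knockouts, and WRKY37 knockout replicate 3 lies at the WT level in the storage protein panel (1.01%).

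The next question was how far the changes of both knockouts coincide. Arabinogalactan peptide on chromosome 10, a cell surface protein, rose from 9.22 ± 1.66 in WT to 44.3 ± 2.7 in the LBD40 and 68.5 ± 16.3 in the WRKY37 knockout. Plasma membrane intrinsic protein 2.9 on chromosome 10, a water channel, rose from 183 ± 9.55 to 437 ± 23.8 and 330 ± 6.42, and Histone-lysine N-methyltransferase ATXR6-like protein on chromosome 3, which modifies histone H3, rose from 2.26 ± 0.132 to 7.97 ± 0.92 and 9.08 ± 1.08. Nucleobase-ascorbate transporter 6-like protein on chromosome 4 fell from 9.84 ± 1.16 to 0.333 ± 0.123 and 0.537 ± 0.271. UDP-glycosyltransferase 76E1 on chromosome 12, with 11.2 ± 4.13 in WT, was listed at 0 in all 6 knockout libraries.

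In both knockouts 573 genes were higher and 460 lower, where independent lists of the same sizes would share 158.8 and 161. Another 92 genes changed in opposite directions, against 320.5 for independent lists; 75 of them were higher in the LBD40 and lower in the WRKY37 knockout. The 2 comparisons use the same WT libraries, and unchanged groups simulated against those libraries shared at most 1 gene called higher and 0 called lower in 100 draws. Those groups called so few genes that independent lists of their sizes would share at most 5.451e-05 and 0.000109, so these counts carry little weight. Across all tested genes, the log2 changes of the 2 knockouts had a correlation of 0.4657 against a mean of 0.5008 in the simulations, and a covariance of 0.1721 against 0.04235. The total of 1033 shared genes was 462 without WT replicate 1, 586 without WT replicate 3, 652 without LBD40 knockout replicate 2, 624 without WRKY37 knockout replicate 1 and 1639 without WRKY37 knockout replicate 3.

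The knockouts were also compared with each other. The RuBP carboxylase small subunit gene on chromosome 2, part of the enzyme that fixes carbon dioxide, had 395 ± 55.3 in the LBD40 and 7.98 ± 5.23 in the WRKY37 knockout, with 180 ± 153 in WT. Cellulose synthase on chromosome 12 (copy 2) had 3.51 ± 0.178 in the LBD40 and 62.2 ± 14.3 in the WRKY37 knockout, with 48.7 ± 4.12 in WT. Of 55 histone genes, 40 were higher in the LBD40 than in the WRKY37 knockout and 1 was lower, and of 56 photosynthesis genes 34 were higher and 2 lower. With an estimated correlation these lists had adjusted p = 0.16 and 0.356.

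In this comparison 4953 of 18346 genes passed (27%), 2363 higher and 2590 lower in the LBD40 knockout, and 1499 of them differed by at least 1 on the log2 scale, 1079 higher and 420 lower. The higher genes outnumbered the lower under several settings. The number was 2282 without LBD40 knockout replicate 1 (1434 higher, 848 lower), 2538 without LBD40 knockout replicate 2 (1418 and 1120), 3275 without WRKY37 knockout replicate 2 (1878 and 1397) and 3147 with the WT libraries left out of the fit (1824 and 1323). With median-ratio scaling 3048 were higher and 2745 lower. The median log2 difference of all genes was -0.081.

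In camera, 11 of the 24 lists passed between the knockouts, each higher in the LBD40 knockout. Histones had a median log2 difference of 1.26 (adjusted p = 1.76e-21; 43 higher and 1 lower adjusted over the list alone; adjusted p = 0.16 with an estimated correlation) and photosynthesis 1.23 (adjusted p = 4.94e-10; 39 and 2 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). Medians of the WRKY (0.484, adjusted p = 6.46e-06), peroxidase (0.434, adjusted p = 5.31e-05), glutathione S-transferase (0.351, adjusted p = 0.000381) and proteinase inhibitor lists (0.351, adjusted p = 0.000308) were above those of the LEA (0.23, adjusted p = 0.0121), jasmonate (0.227, adjusted p = 0.0199), cell wall (0.194, adjusted p = 0.0187), lipid mobilisation (0.156, adjusted p = 0.0263) and starch lists (0.151, adjusted p = 0.0226). In the same order these 9 had adjusted p = 0.16, 0.344, 0.344, 0.16, 0.266, 0.448, 0.694, 0.694 and 0.621 with an estimated correlation. The oil body list, lower than WT in both knockouts, did not pass between them (median 0.163, mean -0.046, adjusted p = 0.584). Seed storage proteins, which did not pass camera (median -0.625, adjusted p = 0.105), passed as lower in the LBD40 knockout with fry (adjusted p = 0.0346). Median, mean and test also differed in sign for abscisic acid genes (median -0.027, mean 0.025, adjusted p = 0.789) and auxin genes (median -0.163, mean 0.033, adjusted p = 0.956).

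The targeted genes themselves could be followed only in part. A gene described as WRKY transcription factor 37, on chromosome 1, had 0.28, 0.7 and 0.92 in WT, 0.23, 0 and 0 in the WRKY37 knockout and 1.11, 1.89 and 0.74 in the LBD40 knockout. It was too low for the genome-wide test; a two-sided exact permutation test of the WRKY37 knockout against WT gave p = 0.1, the smallest that 3 against 3 can give, and its log2 difference was -0.588. The ID recalled in the plan for SlWRKY37 lies on chromosome 2. Of 32 tested WRKY genes, 1 was called higher and 4 lower in the WRKY37 knockout. Those lower included WRKY transcription factor 6 and WRKY transcription factor 8 on chromosome 2. With shortened IDs, whether either is the edited gene cannot be told. A gene described as LOB domain-containing protein 40, on chromosome 5, rose from 12.6 ± 7.44 in WT to 40.9 ± 4.24 in the LBD40 knockout (adjusted p = 0.0169). That description comes from a similar pepper protein and does not show that this is the edited gene, and an edit by Cas9 need not change the amount of RNA. The ID recalled in the plan for SlLBD40 also lies on chromosome 2, and the tested LOB domain genes there did not pass. LOB domain-containing protein on chromosome 2 (copy 2) had 377 ± 103 in WT and 282 ± 5.41 in the LBD40 knockout (adjusted p = 0.16). LOB domain-containing protein 36 on chromosome 2 (copy 2) had 9.79 ± 1.38 and 11.4 ± 0.96 (adjusted p = 0.373).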

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

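Of the tests in this part, those of scaling, of swapped libraries, of leaving out WRKY37 knockout replicate 3, of a larger share of a few WT transcripts, of green tissue and of DNA replication were chosen after the result was seen; the splits of the libraries, the simulated groups and the test of mixed RNA were chosen before.

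The effects of the knockouts on 4953 genes differed in a direct test, which is the difference of the effects since WT cancels. Between them 92 genes were called in opposite directions. In the same test the effect was higher in the LBD40 knockout for 11 gene lists, with median log2 differences of 1.264 for histones, 1.23 for photosynthesis, 0.484 for WRKY transcription factors, 0.434 for peroxidases, 0.351 for glutathione S-transferases, 0.351 for proteinase inhibitors, 0.23 for LEA proteins, 0.227 for jasmonate genes, 0.194 for cell wall genes, 0.156 for lipid mobilisation and 0.151 for starch and raffinose genes. These calls rest on the preset correlation of camera: with an estimated correlation none of the 11 lists passed (adjusted p = 0.16 to 0.694).

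Each comparison of 6 libraries has 10 splits, too few for a share under 0.05. In fits of the 2 groups alone, the real split was the 1 with the largest count in all 3 comparisons. It called 8322 genes for the LBD40 knockout, 802 for the WRKY37 knockout and 3147 between the knockouts, and the highest other splits called 4, 1 and 1.

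The first pattern is that oil body transcripts were lower in both knockouts, by lists that passed camera but had adjusted p = 0.508 and 0.318 with an estimated correlation. With median-ratio scaling the list medians were -1.211 in the LBD40 and -1.271 in the WRKY37 knockout, against -1.251 and -1.238 without it. This scaling would remove an effect of a few abundant transcripts on the scale. The median change of all genes was -0.023 and 0.022 without it and 0.01 and -0.006 with it. So small a shift could not have brought the list medians near 0, so this test decides nothing. A larger share of a few WT transcripts would also lower the other genes in WT, opposite to this pattern. Unchanged groups simulated against the same WT libraries shared at most 0 genes called lower in both, against 460 observed, but they called almost no gene (independent lists of their sizes would share at most 0.000109), so this count decides nothing. Across all tested genes the changes of both knockouts had a correlation of 0.4657, below the simulated mean of 0.5008, and a covariance of 0.1721, above the highest simulated value of 0.04835; chance values of the WT libraries stay open for the oil body genes. Seeds of different lots or maturity could give the same pattern, and since the labels name no lot, this cannot be separated from the genotype, the biological explanation, which was not tested apart from the lot.

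The second pattern is that WRKY37 knockout replicate 3 lies nearer to WT than replicates 1 and 2, with a mean correlation to the WT libraries of 0.951 against 0.9389 and 0.9418. WT RNA mixed into the library would place genes that rose and genes that fell at the same point between the knockout and WT levels. Their median positions were 0.64 and 0.181, a difference of 0.459 (95% bootstrap interval over genes 0.418 to 0.504), which argues against WT RNA as the only source. The differences in replicates 1 and 2 were -0.057 (-0.139 to 0.025) and 0.085 (0.009 to 0.164). Genes were resampled as if independent, so these intervals do not measure the spread between libraries and may be too narrow. A swap with a WT library would leave a WT library out of place, yet all 3 WT libraries correlated best with another WT library. A seed sample of another stage or lot may be involved, which the labels do not give and which was not tested.

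The third pattern is that histone and photosynthesis transcripts were higher in the LBD40 than in the WRKY37 knockout, by lists that passed camera but had adjusted p = 0.16 and 0.356 with an estimated correlation. The smaller of the list medians was 1.077 without WRKY37 knockout replicate 3, so that library alone does not account for the pattern. With median-ratio scaling the smaller median was 1.26. The median difference of all genes was -0.081 without that scaling and -0.016 with it. This shift is small beside the list medians, so the test of scaling could not have come out otherwise. For the photosynthesis part against WT, green tissue in the LBD40 libraries could account for a higher sum of chlorophyll a/b binding and Rubisco small subunit values: the log2 ratio to WT was 0.702 over 41 genes, after 0.319 over the 39 that the fixed list holds, since 2 abundant Rubisco genes missed by the list were added after the first value was seen. The sums were 1034, 1097 and 900.4 in the LBD40 libraries and 475.3, 375.3 and 1014 in WT, so 1 WT library lies in the LBD40 range and the explanation stays open. For the histone part, more cells in DNA replication could raise replication genes as well. Against WT, 19 such genes had a median log2 change of -0.014 (95% bootstrap interval over genes -0.308 to 0.223, 2 higher, 5 lower). The histone median was 0.98, above that interval. Genes were resampled as if independent, so the interval does not measure the spread between libraries. The share of cell cycle and replication genes was 0.427 ± 0.0199% in the LBD40 knockout and 0.627 ± 0.0446% in WT. That wider list also holds a cyclin-dependent kinase inhibitor, so its share does not measure replication alone. The 19 genes did not rise like the histones, but whether more cells were in DNA replication stays open.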

How the results depend on the processing

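The 2 scalings and the 12 narrowed lists, with their values without each library, were added after the data were seen; the other alternatives were planned. The normalization and tool alternatives for counts were not run, as the data hold no counts. None of the genes called with the reported settings changed sign in any alternative. For 231 results on named genes, 3815 settings kept the side of the threshold, 84 lost it and 0 reversed. Depth is unknown, so its effect on low genes was not assessed.

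Requiring a log2 change of at least 1 left 2005, 816 and 1499 genes for the LBD40 knockout, the WRKY37 knockout and the difference between them, by its construction. Fitting only the compared groups gave more genes for the LBD40 knockout (8322) and fewer for the WRKY37 knockout (802) and between the knockouts (3147). With genotype as the only term this leaves each log2 change as it was (medians -0.023, 0.022 and -0.081). The counts therefore differ through the estimated spread and the number of libraries behind it. Leaving out each library in turn gave 4533 to 7641 genes for the LBD40 knockout, 783 to 2629 for the WRKY37 knockout, 2282 to 5192 between them and 462 to 1639 in both, 8 to 11 lists for the LBD40 and 6 to 9 for the WRKY37 knockout, and a log2 difference of -0.754 to -0.461 for WRKY transcription factor 37. With the replicate number as a block, 6040, 1203 and 4117 genes passed, 714 in both, and 10 and 8 lists. Of the 24 lists fixed before the data were examined, 0 passed with an estimated correlation in the LBD40 and 0 in the WRKY37 knockout; of the 12 narrowed ones, LEA genes outside the hydroxyproline-rich family passed in the WRKY37 knockout (adjusted p = 0.0429). With fry 3 fixed lists passed in the WRKY37 knockout and 10 in the LBD40 knockout, 8 of them among the reported ones; the others were LEA proteins (lower, adjusted p = 0.0065) and gibberellin genes (higher, adjusted p = 0.0406). The cause was not tested.

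The more frequent direction also turned. In the LBD40 knockout higher genes outnumbered lower ones with equal library totals (3705 against 3668), with median-ratio scaling (3974 against 3857), and without WT replicate 2 or LBD40 knockout replicate 1. In the WRKY37 knockout lower genes outnumbered higher ones without a low-value filter (688 against 579), with the replicate block (612 against 591), in the fit of 2 groups and without any 1 library other than WT replicate 2, LBD40 knockout replicate 3 or WRKY37 knockout replicate 3. Between the knockouts higher genes led without a low-value filter (2354 against 2064), with median-ratio scaling, in the fit of 2 groups, and without any WT library, LBD40 knockout replicate 1 or 2, or WRKY37 knockout replicate 2. Among genes changed in both, lower ones led without a low-value filter (390 against 353), WT replicate 3 (312 against 274) or WRKY37 knockout replicate 2 (510 against 426). A minimum log2 change of 1 turned all 3 comparisons.

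Some lists that did not pass turned the direction of their test; the values are median log2 changes, each with its range over the 9 left-out libraries, and the cause was not tested. In the LBD40 knockout these were ribosomal proteins without WT replicate 1 (-0.045) or LBD40 knockout replicate 3 (-0.04; range -0.045 to 0.066), and heat stress factors without WT replicate 2 (0.037) or WRKY37 knockout replicate 3 (0.004; range -0.059 to 0.037). In the WRKY37 knockout they were heat stress factors without WT replicate 1 (-0.002), LBD40 knockout replicate 3 (-0.075) or WRKY37 knockout replicate 2 (-0.003; range -0.099 to -0.002) and with fry (-0.075), and large chaperones without WT replicate 1 (0.002) or WRKY37 knockout replicate 1 (0.023; range -0.043 to 0.055) and with fry (0.02). Flavonoid genes turned without WT replicate 2 (0.142) or WRKY37 knockout replicate 1 (0.046; range 0.046 to 0.211). Without WRKY37 knockout replicate 1, lipid mobilisation (0.01; range 0.01 to 0.172) and starch genes (0.015; range 0.015 to 0.12) turned. Without replicate 2 these were cell cycle (-0.015; range -0.015 to 0.143), ethylene (0.019; range 0.005 to 0.079) and peroxidase genes (-0.026; range -0.052 to 0.118). Without replicate 3 these were abscisic acid (0.09; range 0.026 to 0.093) and storage protein genes (0.396; range 0.209 to 0.465).

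Medians of other lists that did not pass changed sign without 1 library while the test kept its direction. In the LBD40 knockout these were storage proteins (range -0.294 to 0.111), glutathione S-transferases (-0.103 to 0.101), LEA proteins (-0.1 to 0.003), abscisic acid (-0.023 to 0.118), auxin (-0.015 to 0.121), cell cycle (-0.077 to 0.029) and ethylene genes (-0.06 to 0.017). In the WRKY37 knockout they were WRKY genes (-0.122 to 0.022), besides the chaperone and peroxidase genes named above.

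For the narrowed lists in the 3 comparisons, 308 settings kept the side of the threshold, 35 lost it, 9 gained it and 8 turned the direction of a test that did not pass, and the cause was not tested. In the WRKY37 knockout these were xyloglucan endotransglucosylases without WT replicate 1 (0.067), WT replicate 3 (-0.012) or WRKY37 knockout replicate 1 (-0.12; range -0.12 to 0.448) and abscisic acid genes without WRKY37 knockout replicate 3 (0.293; range 0.054 to 0.293). Between the knockouts they were abscisic acid genes without LBD40 knockout replicates 1 (-0.01) or 2 (-0.086) or WRKY37 knockout replicate 3 (-0.184; range -0.261 to -0.01), and expansins without WRKY37 knockout replicate 1 (-0.157; range -0.463 to -0.133).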

Other observations

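The narrowed lists and their values without each library, the description families and the tests on chromosomes and on distances in this part were chosen after the data were seen.

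Narrowing the lists separated genes that the wider ones held together. LEA genes outside the hydroxyproline-rich family, whose members share a domain but need not act in dry seeds, had 6 higher and 23 lower of 45 in the LBD40 knockout (median -0.646, camera adjusted p = 0.000477; adjusted p = 0.273 with an estimated correlation) and 3 higher and 26 lower in the WRKY37 knockout (median -1.06, adjusted p = 2.8e-12; adjusted p = 0.0429 with an estimated correlation). Storage proteins outside the lipid-transfer family had 1 higher and 8 lower of 12 in the LBD40 knockout (median -2.35, adjusted p = 3.34e-05; adjusted p = 0.273 with an estimated correlation) and 0 higher and 4 lower in the WRKY37 knockout (median -1.246, adjusted p = 2.92e-05; adjusted p = 0.411 with an estimated correlation). Replicate 3 of the WRKY37 knockout was at the WT level here, with 1.01% of the library in this list against 0.195 and 0.264% in replicates 1 and 2 and 0.997 ± 0.141% in WT; leaving out each of the 9 libraries in turn kept the call, at medians of -1.722 (without replicate 3) to -0.843 (without replicate 1). Of 20 xyloglucan endotransglucosylase genes, 14 rose and 2 fell in the LBD40 knockout (median 1.549, adjusted p = 3.34e-05; adjusted p = 0.273 with an estimated correlation), while 4 rose and 4 fell in the WRKY37 knockout (median 0.168, or -0.012 and -0.12 without WT replicate 3 and WRKY37 knockout replicate 1; adjusted p = 0.839), and between the knockouts 10 were higher in the LBD40 knockout and 3 lower (median 1.289, adjusted p = 6.05e-05; adjusted p = 0.463 with an estimated correlation). Pectin enzymes had 24 higher and 1 lower of 49 in the LBD40 knockout (adjusted p = 1.93e-07; adjusted p = 0.273 with an estimated correlation) and 15 higher and 0 lower in the WRKY37 knockout (adjusted p = 1.57e-06; adjusted p = 0.411 with an estimated correlation). Expansins, which loosen walls without cutting them, had 6 and 5 of 15 higher and 0 lower (adjusted p = 0.00454 and 2.92e-05; adjusted p = 0.273 and 0.398 with an estimated correlation).

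Genes of the glyoxylate cycle and of beta-oxidation, which turn stored oil into sugar, had 4 of 11 higher and 0 lower in the LBD40 knockout (median 0.44, adjusted p = 0.00304; adjusted p = 0.296 with an estimated correlation) and 1 higher and 4 lower in the WRKY37 knockout (median -0.182, adjusted p = 0.135), a list that passed without WRKY37 knockout replicate 1 (median -0.258, adjusted p = 0.00665) and lay nearer to 0 without replicate 2 (median -0.093, adjusted p = 0.542) or 3 (median -0.114, adjusted p = 0.343). Between the knockouts 8 were higher in the LBD40 knockout and 1 lower (median 0.658, adjusted p = 4.41e-05; adjusted p = 0.463 with an estimated correlation). Chlorophyll a/b binding proteins did not pass in either knockout (3 higher and 0 lower of 21, median 0.105, adjusted p = 0.222; 1 higher and 2 lower, median -0.71, adjusted p = 0.0584). The calls depended on single libraries: the list passed as higher in the LBD40 knockout without WT replicate 3 (median 0.561, adjusted p = 0.0185), and as lower in the WRKY37 knockout without WT replicate 1 (median -0.661, adjusted p = 0.0387), WT replicate 2 (median -0.88, adjusted p = 0.00157) or WRKY37 knockout replicate 1 (median -0.579, adjusted p = 0.0404). The medians lay nearer to 0 without WT replicate 2 in the LBD40 knockout (0.02, adjusted p = 0.682) and without WT replicate 3 in the WRKY37 knockout (-0.256, adjusted p = 0.264). Between the knockouts 10 were higher in the LBD40 knockout and 2 lower (median 0.816, adjusted p = 0.00749; adjusted p = 0.58 with an estimated correlation).

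Of 136 families of genes with the same description, tested in both knockouts and both directions (544 tests), 17 passed. In the LBD40 knockout these included 3-ketoacyl-CoA synthase genes, which elongate the fatty acids of waxes, with 8 of 10 higher (adjusted p = 0.0041), and genes described as non-specific lipid-transfer proteins, with 8 of 13 higher (adjusted p = 0.029), while the related family described as lipid-transfer protein and seed storage 2S albumin had 6 of 14 higher and did not pass (adjusted p = 0.426). In the other direction, genes described as RNA binding protein had 11 of 17 lower (adjusted p = 0.0041), while those described as RNA-binding protein (11 of 28, adjusted p = 0.241), RNA-binding (RRM/RBD/RNP motifs) family protein (14 of 37, adjusted p = 0.176) and RNA-binding protein 1-like (2 of 12, adjusted p = 1) did not pass. Genes described as Transducin family protein / WD-40 repeat family protein had 9 of 14 lower (adjusted p = 0.0176), while WD40 repeat (16 of 44, adjusted p = 0.171) and Transducin/WD40 repeat-like superfamily protein (16 of 43, adjusted p = 0.143) did not pass. Carboxypeptidases, which trim proteins, had 8 of 14 higher in the LBD40 knockout (adjusted p = 0.0499) and 7 of 14 higher in the WRKY37 knockout (adjusted p = 0.000923). Glycosyltransferases had 13 of 74 lower in the WRKY37 knockout (adjusted p = 0.0041), although their median log2 change was 0.027. Genes of a family may change together, which can make these adjusted p-values too small, and the families were not run under the alternatives.

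Some genes were at most 0.5 in every library of a knockout and at least 5 in every WT library, or the reverse. There were 13 in the LBD40 and 4 in the WRKY37 knockout, with 3 lost in both. Stretches of a chromosome from another seed background could give such genes in clusters, and the most on 1 chromosome were 3 of 13 in the LBD40 knockout, on each of 2 chromosomes (permutation p = 0.802), and 2 of 4 in the WRKY37 knockout (permutation p = 0.442). A count per chromosome does not measure short stretches. In table order, which follows the chromosomes but could not be checked within one, the nearest pairs in the LBD40 knockout lay 37 and 84 places apart. The mean log2 distance between successive genes was 10.041 against 10.653 in random draws of tested genes (permutation p = 0.0655, adjusted p = 0.131), and 12.538 against 12.253 in the WRKY37 knockout (permutation p = 0.562, adjusted p = 0.562). Numbers this small leave both kinds of stretches open.

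The first principal component (41.6% of the variance) placed the LBD40 knockout libraries at 48.35 to 60.27 and the other 6 between -39.59 and -1.4. The second (22%) placed WT at 22.62 to 37.78 and the WRKY37 knockout at -48.15 to -22.78. The third (10.2%) held WRKY37 knockout replicate 3 at 48.02, with the other 8 libraries between -24.94 and 9.25.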
